A study of Homo sapiens with 3 samples.

How the data were processed

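Poly(A) RNA was sequenced from PC9, a human lung adenocarcinoma cell line, after stable lentiviral delivery of a short hairpin RNA. There were 3 libraries: 1 from cells with the first hairpin against EPB41 (hairpin 1), 1 from cells with the second (hairpin 2), and 1 from cells with a non-targeting control hairpin (shNC). Per the labels, both EPB41 hairpins received virus for depletion of EPB41, so they formed 1 group of 2 libraries against 1 control library. Per the series design text, no condition was replicated. The hairpins are separate cell lines, and every p-value below measures the spread between these 2 lines.

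Reads were aligned with HISAT2 2.0.5 and assigned to genes with featureCounts 1.5.0-p3, per the submitters' processing notes. Those notes name the build hg19, but all 27200 genes in the files carry the gene coordinates of GENCODE release 29 on GRCh38. Coordinates below are therefore given on GRCh38, as in the files. The scaling step, the strand setting, the treatment of reads that map to several genes and the gene filter are not given in the sources used here. Genes with near-identical copies (HLA-B and HLA-F, SAA1 and SAA2, HSPA1A and HSPA1B) and the antisense genes AL596223.1 and AL445490.1 are uncertain for that reason. The same holds where named genes overlap others, as BEST1 does FTH1 and IFITM1 does IFITM2. In the table of all genes, 25 symbols are dates made from gene symbols by a spreadsheet, and none of them is named below.

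The deposited value per gene is a scaled signal, not a count: in each file the authors' values are whole multiples of 1 step after removal of a small constant. The steps were 0.975 for hairpin 1, 0.955 for hairpin 2 and 1.03 for shNC. Division by the step gave whole reads for 100% of values in each library, within a tolerance of 0.005 reads. The hairpin 1 and shNC files list the same 25508 genes in the same order and their steps multiply to 1, so those 2 were scaled together. The hairpin 2 file lists 25743 genes and was scaled apart. Between the files, 24051 genes were shared, 1692 were listed for hairpin 2 alone and 1457 were missing from its file. The lowest read total of a gene listed for hairpin 1 and shNC was 2, so a gene missing from these files had at most 1 read over both.

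The recovered reads came to 24368910 for hairpin 1, 22412927 for hairpin 2 and 22726041 for shNC. All 3 libraries were put on 1 scale with TMM factors (edgeR 4.0.16, R 4.3.3), which were 0.954, 1.08 and 0.973. A normalised read count below is the number of reads divided by the library's relative effective size. Relative to shNC, the effective sizes were 1.05 and 1.09 by TMM, and 1.05 and 1.10 by the authors' scaling as inferred from the steps. The 1.10 assumes that hairpin 2 was scaled in a pair with shNC, as hairpin 1 was, which could not be checked. Intervals are exact Poisson or binomial intervals at the 95% level and cover counting error only.

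The choices of test, filters, gene lists and alternatives were made before the data were examined, except where a test or setting is said to be added. The plan named edgeR for counts and limma for any other unit. Because the deposited unit is a scaled signal, the main test was limma 3.58.1 with an intensity trend on log2(normalised read count + 1), which understates the change of low genes. Genes kept by filterByExpr with a minimum count of 10 were tested, 18016 in all, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fit had 1 residual degree of freedom and took an infinite prior, so each gene was given the trend's spread in place of its own. A gene that differs between the hairpins can therefore be called, and the lone control is assumed to vary like the hairpin lines. Fold changes per hairpin are differences of log2 CPM with a prior count of 2. Rules on 2-fold differences used genes with a mean CPM of at least 1 (the higher expression filter, an alternative, asks for 5). The edgeR quasi-likelihood test, which the plan named for counts, was added on recovered reads after the unit was known. Its legacy form, DESeq2 1.42.0 and voom were set as alternatives beforehand, and the legacy form gave the same numbers of calls.

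Because both hairpins share 1 control library, 100 sets of unchanged libraries were simulated with negative binomial counts. Each set held a simulated control shared by both simulated hairpins, and the real control was not held fixed. A gene's mean was that over all real libraries, and its spread was the fitted trend. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Random lists drew genes independently and were not matched on GC content. The rank of a list therefore describes these libraries and is no p-value. GC content came from the longest transcript of each gene in GENCODE 29 and was known for 99.96% of tested genes. GC correction, an added setting, was applied to every library, shNC included. It removed a loess curve on GC of each library's deviation from the mean of the libraries. On simulated data for the comparison of EPB41 depletion with shNC, with 187 changed genes among 17381 tested, the main test recovered 22.3% of 4-fold and 92.5% of 16-fold changes. All recovered genes had the right direction, and 11 of 118 calls were false. Each simulated gene had the fitted trend's spread, as an infinite prior assumes, with no GC trend or difference between the hairpins. These rates may therefore not hold for the real libraries.

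Genes named below follow a fixed rule: EPB41 and its family; the 12 called genes per direction with the largest smaller fold over both hairpins, at a mean CPM of at least 5; up to 4 members of each of the fixed lists by the same ranking, called members first; ALDOC, CTNNB1, GSK3B, MYC, CCND1 and AXIN2; and the 5 genes that differ most between the hairpins. One gene that the rule selects is not reported here. Genes outside the rule are said to have been chosen after their values were seen. Alternatives covered other scalings, filters, pseudocounts, tools, thresholds, GC correction and each hairpin alone. Alternatives on FPKM were not run, since the files used here hold no FPKM.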

Results

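The transcriptome of PC9 lung adenocarcinoma cells was measured after delivery of hairpins against EPB41, with 24368910 reads for hairpin 1, 22412927 for hairpin 2 and 22726041 for the shNC control. EPB41 encodes protein 4.1R, which links the spectrin and actin skeleton to the plasma membrane. Each condition had 1 library, so values are given per library without a replicate error. The design asks which genes change when EPB41 is depleted, and whether both hairpins give the same change.

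EPB41 (ENSG00000159023, chromosome 1, positions 28887091 to 29120046, GRCh38) was lower in both hairpin libraries than in the control, with the larger difference for hairpin 2, although the log2 fold change of hairpin 1 turned to 0.37 after GC correction (hairpin 2: -0.74). Its normalised read count was 608 (95% interval 560 to 658) with hairpin 1, 389 (352 to 429) with hairpin 2 and 694 (642 to 749) with shNC. Relative to shNC this was 87.5% (78.3 to 97.9%) with hairpin 1 and 56.1% (49.5 to 63.6%) with hairpin 2. These intervals cover counting error of those libraries only. In limma, EPB41 had a log2 fold change of -0.51 (SE 0.57) and an adjusted p of 0.857, and it was not called under any setting tried. Over all settings its adjusted p ranged from 0.741 to 0.979. The paralogs EPB41L1, EPB41L2, EPB41L4B and EPB41L5 were not called either. With EPB41 these 5 family genes gave 0 calls by limma (0 adjusted over the list alone), edgeR and DESeq2. Their normalised read counts with hairpin 1, hairpin 2 and shNC were 3223, 2489 and 2957 for EPB41L1, and 1154, 1548 and 1001 for EPB41L2. For EPB41L4B they were 755, 577 and 433, and for EPB41L5 they were 568, 575 and 523.

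**Figure D1:**
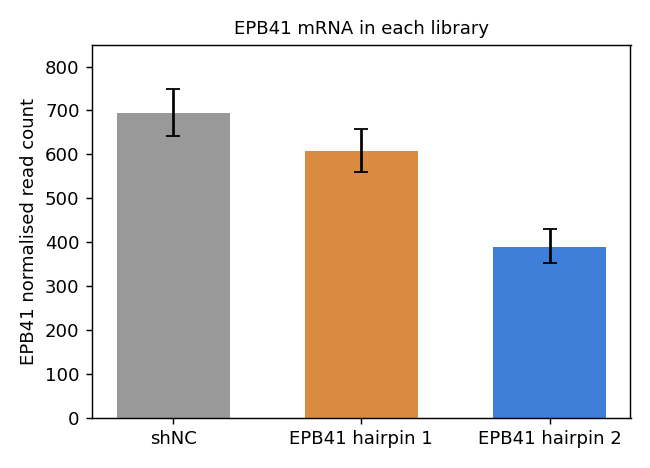
EPB41 normalised read count in the 3 libraries, with exact Poisson 95% intervals as error bars, which cover counting error only. The shNC library is at 694, hairpin 1 at 608 and hairpin 2 at 389; after GC correction the direction of hairpin 1 turns (log2 fold change 0.37).

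Among the genes called higher were several that respond to low oxygen or serve glucose use. ANGPTL4 (chromosome 19, 8363289 to 8374373), a secreted inhibitor of lipoprotein lipase, rose from a normalised read count of 18.8 with shNC to 1223 with hairpin 1 and 904 with hairpin 2 (limma log2 fold change 5.73, SE 0.60, adjusted p 9.8e-18). The stress gene NDRG1 rose from 1881 to 44330 and 9499 (limma adjusted p 5.48e-08), and the oxygen sensor EGLN3 from 239 to 3363 and 1490 (limma adjusted p 2.95e-06). PPFIA4, a liprin that responds to hypoxia, rose from 51.3 to 1114 and 471. Of 20 hypoxia genes outside glycolysis, 5 were called higher and 0 lower, and 13 and 1 when adjusted over the list alone. The 5 became 4 with DESeq2 size factors and 4 after GC correction. The list's median log2 fold change was 1.93 with hairpin 1 and 0.85 with hairpin 2, each above all 10000 random lists. Among 25 genes of glycolysis and glucose transport, 3 rose, also 3 when adjusted over the list alone, and 0 fell. These were the neuronal enolase ENO2 (375 with shNC, 8625 and 2355 with the hairpins), the glucose transporter SLC2A3 (282, 3922 and 1370) and the regulator PFKFB4 (97.4, 1095 and 611). PFKFB3 was not called, at 850, 2920 and 1753. The 3 glycolysis calls were also made after GC correction, with DESeq2 size factors and by edgeR. For 32 nuclear genes of oxidative phosphorylation, limma called 0, also 0 adjusted over the list alone and 0 by edgeR or DESeq2. Their median was -0.00 with hairpin 1 and -0.35 with hairpin 2, and the hairpin 1 value was above 0 with DESeq2 size factors, the higher expression filter or GC correction.

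Some growth factor ligands of the EGF receptor family and targets of MAPK signalling were called lower. Amphiregulin (AREG, chromosome 4, 74445134 to 74455009) fell from a normalised read count of 4876 with shNC to 138 with hairpin 1 and 609 with hairpin 2 (limma log2 fold change -4.06, SE 0.56, adjusted p 8.93e-10). Epiregulin (EREG) fell from 8585 to 198 and 1789 (limma adjusted p 3.13e-09), although the DESeq2 adjusted p of this gene was 0.74, in a range from 3.13e-09 to 0.74 over its alternatives. HBEGF fell from 5457 to 240 and 1214 (limma adjusted p 8.62e-07), and the AP-1 subunit FOSL1 from 5276 to 533 and 1453 (limma adjusted p 0.000471). Of 24 EGFR and MAPK target genes, 7 fell and 1 rose, or 9 and 1 when adjusted over the list alone. The gene that rose was SPRY1, a feedback inhibitor of receptor kinase signalling, at 34.6 with shNC, 186 with hairpin 1 and 194 with hairpin 2, and was called neither with DESeq2 size factors nor by edgeR (highest adjusted p over limma, edgeR and DESeq2 0.0839). This list's median was -1.34 with hairpin 1 and -0.89 with hairpin 2, below all 10000 random lists in both. Of these members, 6 were called lower and 1 higher after GC correction, 5 and 0 with DESeq2 size factors, and 6 and 0 by edgeR. Of 14 receptor kinase and RAS pathway genes, limma called 0 (also 0 adjusted over the list alone, 0 by edgeR and 0 by DESeq2). EGFR itself, which carries an activating mutation in PC9, had 52700 normalised reads with shNC, 19060 with hairpin 1 and 30420 with hairpin 2 (limma adjusted p 0.372). The medians of these receptor genes were 0.38 and 0.07, the latter turning to -0.00 with the higher expression filter.

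DUSP1, a phosphatase of MAP kinases, fell from 3430 normalised reads with shNC to 274 and 494 (limma log2 fold change -3.22, SE 0.56, adjusted p 4.83e-06). The urokinase gene PLAU fell from 19580 to 2554 and 2496 (limma adjusted p 1.04e-05), and the kinase anchor AKAP12 from 10370 to 1104 and 1545 (limma adjusted p 1.08e-05). IL1RL1, the receptor of interleukin 33, fell from 789 to 41.8 and 89.2, and the stress cytokine GDF15 from 25140 to 1442 and 5521. BTBD19, BEST1, GLP2R and the antisense transcript AL596223.1 completed the 12 leading lower genes, with limma adjusted p from 0.00441 to 0.00761. These last 4 were not called with DESeq2 size factors. Of 20 YAP and TAZ target genes, 5 fell and 1 rose, or 6 and 1 when adjusted over the list alone. Members were the growth arrest gene GADD45A (9908 with shNC, 1483 and 3434 with the hairpins), ANKRD1 (2060, 115 and 776), CTGF (386, 56.8 and 123) and TGFB2 (2585, 451 and 758). GADD45A was called in 3 and ANKRD1 in 2 of 5 alternatives. The list's median was -1.06 with hairpin 1 and -0.44 with hairpin 2, above 0 and 22 of 10000 random lists. The list's 5 lower calls became 0 with DESeq2 size factors and 1 after GC correction. CTGF and TGFB2 were the 2 of 16 TGF-beta readout genes that fell, and 0 rose (1 and 2 higher and lower when adjusted over the list alone). These 2 calls became 0 with DESeq2 size factors, after GC correction and with the higher expression filter, and CTGF was called in 1 and TGFB2 in 3 of 5 alternatives. The median of that list was above 0, at 0.76 and 0.30, and fell to 0.23 and 0.19 after GC correction. Among 17 immediate early genes, DUSP1 and ATF3 fell and FOS rose (2 lower and 2 higher when adjusted over the list alone). The medians were -0.55 and -0.72, and -1.15 and -0.93 after GC correction. ATF3 went from 1457 to 152 and 483 and was called in 2 of 5 alternatives. FOS went from 239 to 1486 and 510. FOS had a limma adjusted p of 0.0479 and was called in 0 of 5 alternatives.

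Among 28 NF-kB targets and cytokine genes, 7 fell and 3 rose, or 10 and 4 when adjusted over the list alone. The acute phase genes SAA1 (419 with shNC, 2476 with hairpin 1, 3290 with hairpin 2) and SAA2 (167, 679 and 1192) and the complement gene C3 (3383, 18920 and 13510) were higher. Interleukin 1 alpha (IL1A) fell from 357 to 6.97 and 92.1. Interleukin 6 (IL6), at 1345, 14.9 and 454, and the chemokine CXCL8, at 26290, 537 and 10150, also fell, and were chosen after their values were seen. The median of the list was -1.33 with hairpin 1, below all random lists. With hairpin 2 it was -0.10, with a mean of 0.13 of the opposite sign, and with library size scaling it turned to 0.05. The 7 lower calls became 0 with DESeq2 size factors, 0 with the DESeq2 test and 0 after GC correction, and the 3 higher calls became 1, 3 and 2. C3 was called neither with DESeq2 size factors nor after GC correction, and SAA2 not with DESeq2 size factors. IL1A, IL6 and CXCL8 were each called in 2 of 5 alternatives. The medians of 27 ATF4 and unfolded protein response genes were -0.62 and -0.57, above 10 and 0 of 10000 random lists. Of these genes, 2 fell (6 when adjusted over the list alone) and 0 rose. These were the cystine transporter SLC7A11, at 20430, 1794 and 6173, and CHAC1, at 1510, 192 and 821, which was called in 0 of 5 alternatives, against 2 of 5 for SLC7A11. The 2 lower calls became 0 with DESeq2 size factors, the DESeq2 test, the higher expression filter and GC correction, and 1 by edgeR. SLC7A11 was also the 1 of 21 NRF2 targets that fell (2 when adjusted over the list alone), where medians were -0.36 and -0.77. GDF15 was the 1 of 24 p53 targets that fell, and adjusted over the list alone 4 were lower and 3 higher. The p53 medians were -0.36 and -0.12, and the latter had a mean of 0.01 and turned to 0.03 with library size scaling.

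The calcium-binding alarmin gene S100A8 (chromosome 1, 153390032 to 153391188) rose from 268 normalised reads with shNC to 4694 and 4869 (limma log2 fold change 4.15, SE 0.54, adjusted p 5.14e-11). CES1, a carboxylesterase, rose from 36.6 to 1094 and 766 (limma adjusted p 2.04e-11), and the heat shock gene HSPA2 from 55.5 to 2031 and 588 (limma adjusted p 3.83e-10). COL17A1, a collagen of hemidesmosomes, rose from 16.8 to 311 and 440 (limma adjusted p 1.29e-08), and SERPING1, an inhibitor of complement C1, from 5.23 to 118 and 308 (limma adjusted p 1.33e-08). The airway secretory genes BPIFA1 (26.2, 277 and 337) and WFDC2 (80.6, 755 and 769) rose as well. STC1 (34.6, 759 and 347), PDZK1IP1 (133, 1483 and 1449), BTN3A3 (26.2, 293 and 624) and THEMIS2 (9.42, 212 and 137) completed the 12 leading higher genes. Every one of these 12 was also called with DESeq2 size factors, library size scaling, GC correction, edgeR and DESeq2. Of 16 lung lineage genes, 3 rose (3 when adjusted over the list alone) and 0 fell, with medians of 0.67 and 0.58. They were the mucin MUC5B (303, 5162 and 2365), the ciliated cell regulator FOXJ1 (13.6, 63.7 and 229) and LAMP3 (177, 280 and 2920), an alveolar and interferon-inducible gene. MUC5B alone of these was called after GC correction or with DESeq2 size factors. LAMP3 was called in 2 of 5 alternatives, and its log2 fold change was 0.66 with hairpin 1 against 4.03 with hairpin 2. Among 32 integrin and adhesion genes, COL17A1 and MCAM rose and PLAU fell (2 higher and 2 lower when adjusted over the list alone), with medians of 0.29 and 0.20. MCAM was called in 1 of 5 alternatives.

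Genes of Wnt signalling were examined in fixed lists of targets and components. GSK3B and beta-catenin (CTNNB1), and ALDOC of the glycolysis list, were fixed beforehand as genes to report, and 0 of these 3 were called. ALDOC, a glycolytic aldolase, had 512 normalised reads with shNC, 1812 with hairpin 1 and 454 with hairpin 2 (limma log2 fold change 0.82, SE 0.56, adjusted p 0.681). GSK3B had 3654, 2488 and 3133 (limma adjusted p 0.902), and CTNNB1 had 5739, 5603 and 5843 (limma log2 fold change -0.00, SE 0.53, adjusted p 0.999). The targets MYC (7711, 1952 and 4529, limma adjusted p 0.199), CCND1 (11640, 6310 and 10430, limma adjusted p 0.833) and AXIN2 (8.38, 44.8 and 44.1, limma adjusted p 0.19) were not called. Of 24 Wnt target genes, 2 rose and 1 fell, or 7 and 2 when adjusted over the list alone. The growth factor BMP4 (47.1, 256 and 276) and the feedback inhibitor NKD1 (12.6, 151 and 49.9) were higher and FOSL1 was lower. Of 44 Wnt pathway components, 3 rose and 0 fell, or 4 and 1 when adjusted over the list alone. These were the ligands WNT11 (4.19, 68.7 and 37.4) and WNT3A (5.23, 62.8 and 37.4) and the secreted antagonist SFRP1 (306, 1153 and 1340). Medians were 0.61 and 0.48 for targets and 0.69 and 0.37 for components. These stood above 9946 and 9987 of 10000 random lists for targets, and above 9999 and 9997 for components. BMP4 and SFRP1 were called in 3 of 5 alternatives, NKD1 and WNT11 in 2, and WNT3A in 0. After GC correction the higher calls of both lists became 0, and the medians were 0.26 and 0.32 for targets and 0.26 and 0.25 for components.

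Of 18 mesenchymal genes, 4 rose (8 when adjusted over the list alone) and 0 fell (2 over the list alone). They were fibronectin FN1 (12470 with shNC, 34650 and 76450 with the hairpins), the collagen COL6A1 (433, 3170 and 990), SPARC (0, 34 and 15 reads) and ACTA2 (1, 28 and 36 reads). The medians were 1.5 and 0.95, above all random lists, which were not matched on GC content. After GC correction the medians were 1.05 and 0.68. With DESeq2 size factors or after GC correction 0 members were called. By edgeR 2 were called, and 1 by DESeq2. Of 28 epithelial genes, the tight junction gene CLDN1 fell, from 4957 to 368 and 2661, and 0 rose (2 lower and 2 higher when adjusted over the list alone). CLDN1 was called in 1 of 5 alternatives, with adjusted p up to 0.499, and the lower call was absent with DESeq2 size factors, GC correction, edgeR and DESeq2. Keratin 19 (KRT19), at 22640, 92350 and 49990, was not called (limma adjusted p 0.0837). The epithelial medians were 0.15 and -0.21, and the former turned to -0.10 after GC correction. Of 25 membrane skeleton genes, spectrin SPTBN4 rose (15.7, 165 and 111) and 0 fell (2 higher and 0 lower when adjusted over the list alone). SPTBN4 was not called after GC correction. The medians of that list were 0.11 and -0.04, the latter with a mean of 0.16 and turning to 0.09 with library size scaling.

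**Figure D2:**
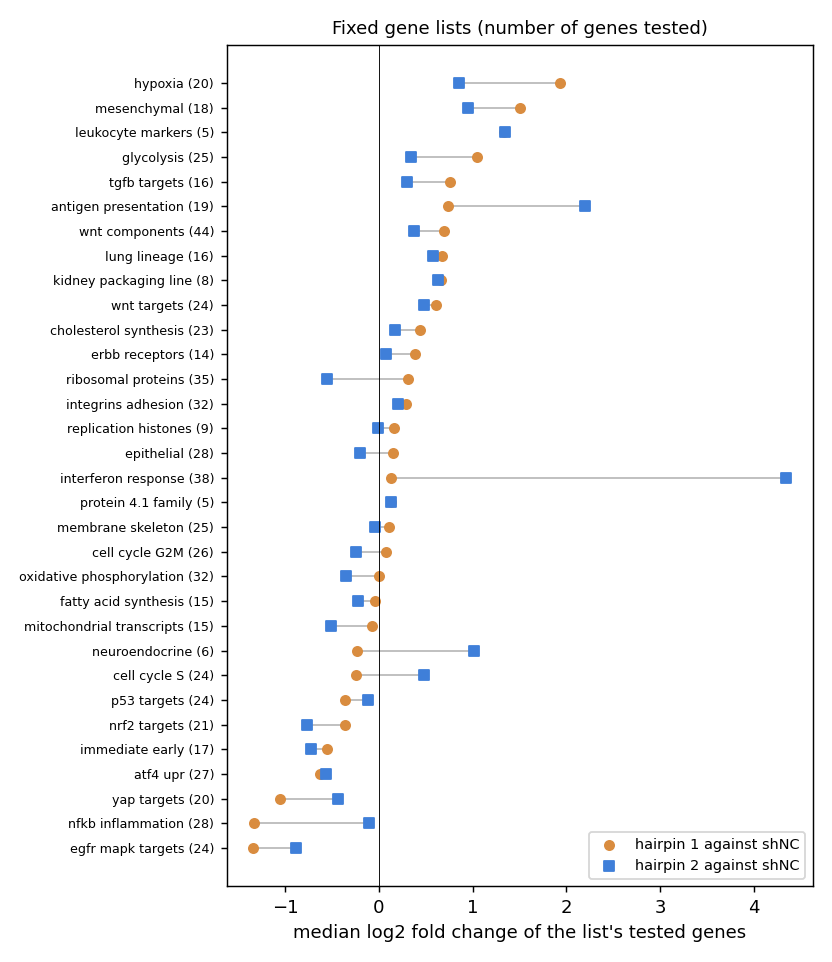
Median log2 fold change of each fixed gene list of at least 5 tested genes, with hairpin 1 as circles and hairpin 2 as squares, both against shNC. The hypoxia list lies at 1.93 and 0.85, the EGFR and MAPK targets at -1.34 and -0.89, and the interferon list at 0.13 and 4.34.

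Across 18016 genes, limma called 416 at an adjusted p under 0.05, with 334 higher and 82 lower. Of these, 308 were at least 2-fold higher and 78 at least 2-fold lower in both hairpin lines, and 8 had opposite signs in the lines. An unadjusted p under 0.05 was reached by 1975 genes. The edgeR quasi-likelihood test called 325 genes, 253 higher and 72 lower, 303 of them shared with limma, and DESeq2 called 198, all shared. The number of calls ranged from 0 to 597 over the settings tried, and was 92 with DESeq2 size factors and 101 after GC correction. With shNC as the lone library 416 genes were called, against 0 for hairpin 1 and 37 for hairpin 2 as the lone library. At an unadjusted p under 0.05 these 2 splits had 2304 and 215 genes, and edgeR and DESeq2 were not run on them.

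The hairpins were next compared with each other by a rule of size alone, since 1 library each allows no test. Among 14512 genes, 4305 lay at least 2-fold from shNC with hairpin 1 (2251 higher, 2054 lower) and 1919 with hairpin 2 (1418 higher, 501 lower). In both, 1000 genes were at least 2-fold higher and 319 at least 2-fold lower, and 26 were 2-fold apart in opposite directions. Simulated unchanged libraries, whose hairpins shared 1 simulated control, gave means of 547 and 352 genes. The observed number lower in both was within the simulated range of 306 to 418. Independent lists would share 220 and 70.9. Across genes, which are not independent replicates, the log2 fold changes of the hairpins had a Pearson correlation of 0.648 and a Spearman correlation of 0.662, against simulated means of 0.5 and 0.481. The same sign was seen for 74% of genes, against 66.7% in simulation. The covariance was 0.552 against a simulated 0.299 (0.285 to 0.311), a difference of 0.253. With 1 control library the control could not be split, and part of the excess may come from it.

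**Figure D3:**
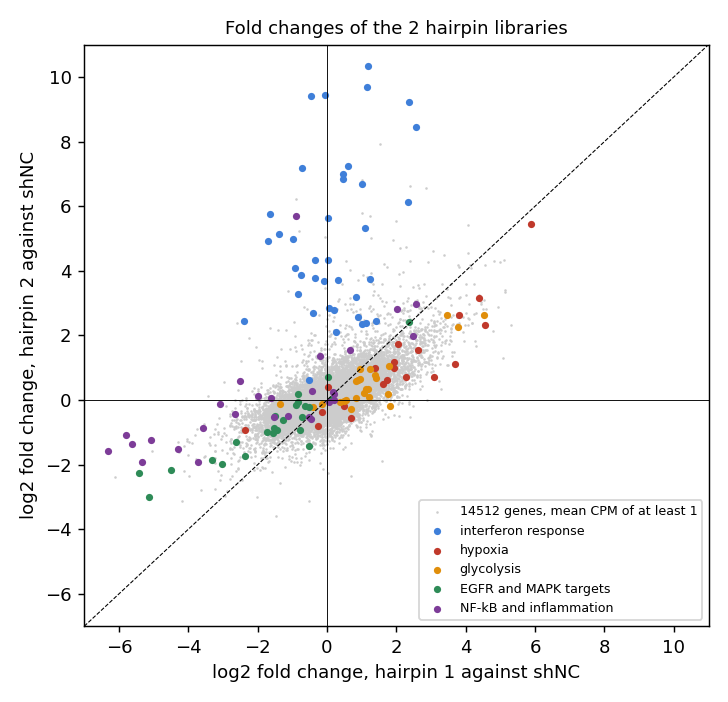
Log2 fold change of hairpin 2 against that of hairpin 1, each relative to shNC, for 14512 genes (grey) and 5 of the gene lists (colours); the dashed line marks equal values. Interferon genes spread along the vertical axis with a median of 4.34 for hairpin 2 and 0.13 for hairpin 1.

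Interferon-stimulated genes separated the 2 hairpin lines. The antiviral gene OAS2 (chromosome 12, 112978395 to 113011723) had 14810 normalised reads with hairpin 2, 13.9 with hairpin 1 and 19.9 with shNC. TRIM22 had 4272, 3.98 and 4.19 in the same order, IFI27 had 8077, 11.9 and 4.19, IFI44L had 6028, 13.9 and 5.23, and IFIT1 had 13260, 53.8 and 90.0. All 38 tested interferon-stimulated genes were higher with hairpin 2 than with shNC, 37 of them at least 2-fold, with a median log2 fold change of 4.34, above all 10000 random lists. With hairpin 1 the median was 0.13 (0.04 with the 1 gene absent from shNC at its bound), 10 genes were at least 2-fold higher and 4 at least 2-fold lower. Some members were higher in both lines, among them IFI6 (28120 with hairpin 2, 238 with hairpin 1, 45.0 with shNC), IFITM1 (9181, 151 and 24.1), OAS1 (8429, 606 and 119) and BST2 (13220, 6486 and 2426). The limma test called 23 of the 38 higher and 0 lower, or 35 when adjusted over the list alone, and 8 of the 23 were at least 2-fold higher in both lines. These calls were 29 by edgeR, 2 with DESeq2 size factors, 1 by DESeq2, 1 after GC correction and 0 with the higher expression filter. Of the members named, OAS1 was called in 4 of 5 alternatives, IFITM1 in 3, BST2 in 1 and the other 6 in 2 each.

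Of 19 antigen presentation genes, 15 lay above shNC with hairpin 1 and all 19 with hairpin 2, a difference between the hairpins that was not tested. Of the 19, limma called 12 neither way, 7 rose (10 when adjusted over the list alone) and 0 fell, with a median of 0.74 for hairpin 1 and 2.20 for hairpin 2. HLA-B had 8559 normalised reads with hairpin 2, 646 with hairpin 1 and 87.9 with shNC (limma log2 fold change 4.73, SE 0.56, adjusted p 1.48e-13). HLA-F had 734, 119 and 26.2, and the immunoproteasome subunit PSMB9 had 2769, 692 and 227. HLA-B was not called by DESeq2 (adjusted p 0.218). The 7 calls became 2 with DESeq2 size factors, 4 by DESeq2, 6 by edgeR, 1 with the higher expression filter and 1 after GC correction, which was HLA-B, and 5 of the 7 were at least 2-fold higher in both lines.

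For proliferation, ribosome and mitochondrial genes, differences between the hairpins were not tested. For 24 S phase genes the median was 0.48 with hairpin 2, above 9999 of 10000 random lists, and -0.24 with hairpin 1. The helicase gene MCM6 had 1882 normalised reads with hairpin 2, 1439 with hairpin 1 and 722 with shNC, and CDC6, which loads the helicase, had 1513, 605 and 2228. For 26 genes of G2 and M phase the medians were -0.24 with hairpin 2, above 653 of 10000 random lists, and 0.07 with hairpin 1, above 7803 of them, where the mean was -0.03. The 35 ribosomal protein genes had medians of -0.56 with hairpin 2 and 0.31 with hairpin 1. These stood above 1 and 9447 of 10000 random lists. RPL5 had 12970, 25480 and 26390, and RPL6 had 16800, 26200 and 31540. The 15 mitochondrial transcripts had medians of -0.51 with hairpin 2 and -0.08 with hairpin 1, the latter turning to 0.17 after GC correction. In none of these 4 lists did limma (also adjusted over the list alone), edgeR or DESeq2 call a gene, and mitochondrial transcripts took 3.66% of reads with hairpin 2, 4.99% with hairpin 1 and 5.23% with shNC.

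Lipid synthesis lists gave 0 calls by limma, edgeR and DESeq2. The 23 cholesterol genes had medians of 0.44 with hairpin 1 and 0.17 with hairpin 2, the latter turning to -0.02 after GC correction, and 0 members passed when adjusted over the list alone. INSIG1, a sensor of sterols, had 4112, 1270 and 751 normalised reads with hairpin 1, hairpin 2 and shNC (limma adjusted p 0.0998). The 15 fatty acid genes had medians of -0.04 and -0.23, the former turning to 0.01 with the higher expression filter. Of these, 1 was higher when adjusted over the list alone, and FASN had 28780, 16240 and 10440 (limma adjusted p 0.438).

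Among markers of other cell types, the lung lineage aside, 2 genes were called. Of 5 leukocyte markers tested, 0 were called (0 adjusted over the list alone), with medians of 1.33 with hairpin 1 and 1.34 with hairpin 2. CD14, the most abundant of them, had 84.7, 82.5 and 31.4 normalised reads with hairpin 1, hairpin 2 and shNC. Of 4 endothelial markers, CDH5 fell, from 998 to 144 and 288, and 0 rose (1 lower when adjusted over the list alone). CDH5 was not called with DESeq2 size factors, and the list had 0 calls there and with the higher expression filter. The endothelial medians were 1.10 and 1.00, turning to -0.82 and -0.59 with the higher expression filter. Of 3 fibroblast markers 0 were called (1 higher adjusted over the list alone), with medians of 1.13 and 0.59. FBLN1, the most abundant, had 15830, 10880 and 7206 normalised reads. For 8 genes of kidney packaging cells, used to make lentivirus, 0 were called (1 higher adjusted over the list alone) and medians were 0.66 and 0.64. Of 6 neuroendocrine genes, ENO2 rose and 0 fell (1 higher adjusted over the list alone), with medians of -0.23 and 1.01, the former with a mean of 0.38 and turning to 2.05 with the higher expression filter. Of 9 replication histone genes 0 were called (0 over the list alone), with medians of 0.16 and -0.01. The former turned to -0.05 after GC correction, and the latter, with a mean of 0.27, turned to 0.13 with library size scaling and 0.77 with the higher expression filter. By edgeR and DESeq2, the lists with 0 limma calls had 0 calls too.

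Between the 2 hairpin libraries, 2370 genes were at least 2-fold apart, 985 higher with hairpin 1 and 1385 higher with hairpin 2. Of the 26 genes that were 2-fold from shNC in opposite directions, 22 were lower with hairpin 1 and higher with hairpin 2, and 4 the reverse. IFIT3 was among the 22, at 44.8 normalised reads with hairpin 1, 7904 with hairpin 2 and 143 with shNC, and was chosen after its values were seen. It was called higher by limma (adjusted p 0.0253) and in 1 of 5 alternatives. Fold changes also followed the GC content of the genes. Across 11284 genes, the Spearman correlation of log2 fold change with GC content was 0.571 for hairpin 1 and 0.318 for hairpin 2. Medians ran from -0.93 in the lowest of 10 bins of GC content to 0.64 in the highest with hairpin 1, and from -0.23 to 0.28 with hairpin 2.

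**Figure D4:**
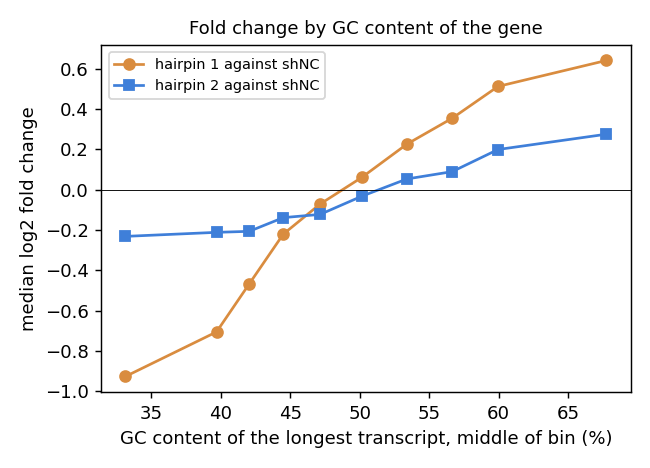
Median log2 fold change against shNC in 10 bins of genes by GC content, for hairpin 1 (circles) and hairpin 2 (squares). Hairpin 1 runs from -0.93 to 0.64 and hairpin 2 from -0.23 to 0.28.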

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

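Of the tests in this part, those on leukocyte genes, on EPB41 depletion, on the extent of EPB41 loss, on GC correction with the prior held infinite and on the fold kept after GC correction were chosen after the results were seen.

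Genes listed for the hairpin 2 library alone were left out of the comparisons, yet 14 of them had at least 20 reads there, against at most 1 read over the other 2 libraries. The interferon genes themselves were among them: IFNL3 had 260 reads, IFNB1 had 113 and the pseudogene IFNL3P1 had 30. The interferon-stimulated genes XAF1, CMPK2, RSAD2 and CXCL11 had 1494, 596, 255 and 100 reads, RTP4 had 121, and the guanylate-binding proteins GBP4 and GBP5 had 87 and 43. The antisense gene AL445490.1 had 119 reads, which cannot be told from reads of the overlapping IFI6 because the strand setting is not given. HSPB9 had 34 reads, the chemokine receptor CCR1 had 26 and the potassium channel regulator ABCC9 had 20. IFNL3 reads are uncertain, since near-identical copies of this gene exist.

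The first pattern weighed is the interferon response of the hairpin 2 line. Blood cells mixed into that culture would bring their own transcripts, but the summed leukocyte markers with hairpin 2 were 1.01 times those with hairpin 1, with CD14 at 82.5 and LYZ at 2.88 normalised reads. Scaling or GC content did not account for it either, because the lowest median log2 fold change of the interferon list was 4.31 over 4 scalings, the higher expression filter and GC correction. EPB41 depletion itself stays open: the median with hairpin 1 was 0.133, but EPB41 there was 87.5% of shNC and above shNC after GC correction (log2 fold change 0.37), so that a response to deeper loss cannot be told apart from a response to hairpin 2 or its virus. A candidate explanation that was not tested is an antiviral response to that hairpin or viral preparation.

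The second pattern is that changes were larger with hairpin 1 and followed GC content. If GC bias were the whole cause and the correction removed all of it, hairpin 1 would not exceed hairpin 2 afterwards. Yet hairpin 1 kept 3170 genes at least 2-fold from shNC against 1745, a ratio of 1.82 (2.24 before). GC content may thus account for part of the excess. Whether a GC trend was left after the correction was not checked, so GC bias as the whole cause stays open. The extent of EPB41 loss stays open: the line with the higher EPB41 had 2.24 times as many such genes, but this ratio is the pattern itself, and the order of EPB41 rests on 1 library per hairpin. A difference in culture, library preparation or clonal history between the lines stays open too, and no biological explanation was tested on other data.

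The third pattern is the change common to both hairpins. The covariance of the log2 fold changes exceeded the mean of the shared-control simulation by 0.253, although the 319 genes at least 2-fold lower in both lay inside the simulated range of 306 to 418; the simulation covers only noise of the spread between the 2 hairpin libraries, so a control culture that deviates by more stays open. After GC correction all 416 called genes kept their direction and 91.3% of the median absolute log2 fold remained (2.62 before, 2.39 after). The fitted GC curve was thus small beside the folds of these genes. Because they were picked for large folds, this outcome was largely set beforehand. It cannot decide whether GC bias was the whole cause for these called genes. Only 23.1% were still called, as the limma prior fell from infinite to 17 degrees of freedom (median SE 0.594 before, 0.5 after), and 85.1% were with the prior held infinite, so the lower prior accounts for most of the loss, while the share of calls that GC bias may explain stays open. With 3 ways to choose the lone library, only 1, the real grouping with shNC alone, gave as many calls. So few splits cannot give a share under 0.05. At an unadjusted limma p under 0.05 the split with hairpin 1 alone had the most genes. The calls thus do not show that shNC stands furthest apart, and EPB41 depletion stays open.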

How the results depend on the processing

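The settings edgeR quasi-likelihood, pseudocounts, robust moderation, the authors' scaling, the deposited values as they stand, GC correction, the same with the prior held infinite and genes listed in any file were added after the data were seen. The count of 416 called genes (334 higher, 82 lower) was within 1.5 times of itself under library size scaling (311) and the inferred authors' scaling (308). The same held for edgeR quasi-likelihood (325), its legacy form, set beforehand (325), and the likelihood ratio test (289). Both quasi-likelihood forms gave 253 higher and 72 lower calls, with 303 shared with limma, so they count as 1 alternative. Pseudocounts of 0.5 and 8 (413 and 311), the deposited values (409) and genes in any file (394) also stayed within that range. So did robust moderation, which called the same 416 genes. An adjusted p under 0.1 (597) can only add calls, and a 2-fold rule in both lines (386) can only remove them. These 2 settings therefore say little about stability. It was smaller with DESeq2 size factors (92; 81 higher, 11 lower), upper quartile factors (43; 38 and 5), a mean CPM of at least 5 (39; 31 and 8), DESeq2 (198; 173 and 25), voom (115; 72 and 43) and GC correction (101; 74 and 27). With no filter, limma called 0 of 24051 genes (0 higher, 0 lower), where 1987 had an unadjusted p under 0.05 and no other tool was run. Among lower genes alone, library size scaling gave 52 and the looser threshold 124. In the limma trend fits with fewer than 100 calls the prior fell from infinite to 21.1, 15.2, 17.4 and 1.47 degrees of freedom, and to 17 after GC correction, so each gene's own spread between the hairpins counted more. With the prior held infinite, GC correction gave 512 calls (364 higher, 148 lower). The rule of 2-fold in both lines (1319 genes) gave 3141 genes with no filter (1854 higher, 1287 lower), 796 with a mean CPM of at least 5 (610 and 186) and 3180 at 1.5-fold (2019 and 1161), as the number of genes and the threshold change by construction. With 1 hairpin alone the rule gave 1919 to 4305 genes. The correlation of 0.648 moved to 0.6251 with a mean CPM of at least 5 and 0.638 after GC correction. Under the same filter, genes 2-fold apart between the hairpins numbered 1565 and those in opposite directions 13, with fewer genes tested. With 1 hairpin alone the log2 fold change ran from -0.4574 without hairpin 2 to 9.403 without hairpin 1 for OAS2, from -0.0483 to 9.432 for TRIM22, from -0.7224 to 7.171 for IFIT1 and from -1.635 to 5.765 for IFIT3, so that the calls of these 4 genes rest on hairpin 2. Among single named genes, 1034 values were labelled unchanged, 135 lost a call, 3 gained one, 21 moved and 4 reversed. These values include each gene's fold with 1 hairpin alone, which was set against no threshold. Such a fold was labelled unchanged when it lay within the spread of the hairpins around the joint fold. Almost any single hairpin does so by construction. Among counts of list members, 90 stayed, 82 were lower and 2 higher. Of list medians, 180 stayed and 23 moved, but the 180 include the medians with 1 hairpin alone. Those could not move, because a single hairpin's median always lies within the allowed distance of the mean of both. No paired analysis was possible because there is 1 control library. Leaving out a hairpin leaves no residual degrees of freedom, so those values have no test. The FPKM alternatives set beforehand were not run, since the files used here hold no FPKM, and no leukocyte median exists at a mean CPM of at least 5, where no member was left. Unless said otherwise, the cause was not tested. At this depth genes with few reads, such as SPARC, have wide counting error.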

Other observations

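Genes in this part were chosen after their values were seen, and no list of them was fixed. S100A9, the partner of S100A8, rose from 4230 normalised reads with shNC to 22430 with hairpin 1 and 20410 with hairpin 2 (limma log2 fold change 2.34, SE 0.53, adjusted p 0.00139), whereas S100P stood at 7934, 8683 and 7426 (limma adjusted p 0.997). The complement proteases C1R (311, 1417 and 4928) and C1S (740, 1862 and 8853) rose (limma adjusted p 8.76e-06 and 0.00094), as did ceruloplasmin CP (137, 967 and 1682) and the airway gene BPIFB1 (400, 1797 and 1950), with limma adjusted p of 7.53e-06 and 0.00586. The heat shock genes HSPA1A (578, 7985 and 2797) and HSPA1B (388, 4630 and 1811) rose as well (limma adjusted p 8.54e-06 and 3.84e-05), though reads of these near-identical genes cannot be assigned with certainty. With DESeq2 size factors, library size scaling, GC correction, edgeR and DESeq2, 5 of 5 alternatives called S100A9, C1R, CP, HSPA1A and HSPA1B, 4 called BPIFB1 and 3 called C1S.

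The amino acid transporter gene SLC38A2 fell from 37830 normalised reads with shNC to 3999 with hairpin 1 and 14480 with hairpin 2 (limma log2 fold change -2.31, SE 0.53, adjusted p 0.00164), and SLC7A1 from 14840 to 3127 and 6330 (limma adjusted p 0.0453). SLC38A2 was called in 2 and SLC7A1 in 0 of the 5 alternatives. Further interferon-inducible genes differed between the hairpins. The helicase gene DDX60 had 539, 247 and 5563 normalised reads in the same order, and the antiviral gene SAMD9 had 1992, 376 and 10760, neither called by limma (adjusted p 0.435 and 0.998), though edgeR called DDX60 (adjusted p 0.00933).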
